A study of Homo sapiens with 4 samples.

How the data were processed

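DNA methylation was profiled by methyl-capture sequencing, in which fragments bound by a methyl-CpG-binding domain protein are pulled down and sequenced, so that the reads report methylated stretches and not single cytosines. The cells were human subcutaneous preadipocytes from a commercial supplier, differentiated for 15 days and then exposed to DMSO or to 100 nM guadecitabine, a DNA methyltransferase inhibitor that releases decitabine. The labels describe the dosing as 3X daily without saying whether this means doses per day or days of dosing. DNA was taken on day 4. The labels give 2 samples of DMSO and 2 samples of guadecitabine, and nothing in them says whether the samples of a group came from separate cultures.

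The file used here is 1 table of the whole series. It pairs genomic regions with the transcripts they overlap, over 21 columns. Per the file name, the authors obtained the regions with methylAction and annotated them with Goldmine. Per the submitters' processing notes, Bowtie2 2.2.9 and R 3.3.1 were used, and the builds GRCh38.p5 and hg19 are named with no role. Per the links inside the file, its coordinates are hg38, and all positions below are 1-based hg38 positions as the file gives them. The table holds no read count, group mean, fold change, p-value or direction for any region: 0 of the 21 columns name a sample or group and 0 give a fold, count or p-value. The sequencing depth of the 4 samples is therefore unknown, and no value below has a replicate error between samples. The selection of the regions (all methylated regions, or only those that differed between the groups) and its threshold are not given in the sources used here, so the regions are called listed regions throughout.

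The deposited overlap columns are percentages: the percent of a region that lies in a transcript, in its promoter and in its 3′ end, and a string with the percent in each exon and intron. The deposited overlap in base pairs was recomputed from the coordinates and matched in every pair of region and transcript. Every pair with a promoter percentage above 0 started no more than 499 bp downstream of the transcript start, and the pair reaching farthest upstream among regions wholly inside a promoter started at -968 bp. A region had to overlap the transcript itself to be in the table. The promoter class here is therefore a region that reaches into the transcript near its start, and regions lying only upstream were not analysed here. A region was counted a single time however many transcripts it overlapped, with the priority promoter, 3′ end, exon, intron, on any overlap above 0%. Only the 22 autosomes were analysed, since the cells come from a donor.

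Each region carries its number in the authors' own list. The numbers run through the chromosomes in order, reach the end and then begin again at chromosome 1, giving 2 passes. The table says nothing about what the passes stand for, and no direction is assigned to them here. Some numbers are missing from the table, which does not say why. They were taken as regions that overlap no transcript, and were counted between 2 listed regions of the same pass and chromosome. This reading was not checked, and a region dropped for another reason would be counted with them. The shares of regions overlapping a transcript and the counts over long stretches rest on it. Numbers that fall between the last listed region of a chromosome and the first of the next belong to either, and were left out of the chromosome totals, which are therefore lower bounds.

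The 15 lists, the 4 gene contexts with their overlap alternatives, and the random lists with their backgrounds were set before the data were examined. Every comparison between the passes, the count over long stretches, the profile along transcripts and the gene families were devised after the table was seen. A correlation over chromosomes between the share of the first pass and the share in transcripts was also computed and is not reported, because the long stretches drove it. The planned tests between guadecitabine and DMSO, which needed counts or values per sample, were replaced by descriptions of the regions. Shares are given with exact Clopper-Pearson intervals at the 95% level, which treat regions as independent and cover counting error only, and with the SD over the 22 autosomes. Differences between passes were tested by flipping the sign of each autosome's difference at random in 100000 resamples (two-sided permutation test, smallest possible p 1e-05). The 4 gene contexts were adjusted together by the Benjamini-Hochberg method.

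Gene lists (15) were compared with 10000 random lists of autosomal protein-coding genes matched on gene length in 20 bins drawn without replacement, which is a two-sided permutation test of list membership within length bins (smallest possible p 0.0002), adjusted over the 15 lists. Gene lengths and current symbols came from the RefSeq table of assembly GRCh38.p14. No coordinate of it is printed. Of 16361 protein-coding symbols in the deposited table, 15673 (95.8%) matched 1 of its 19126 autosomal protein-coding genes, 14920 of them under the current symbol. A gene whose symbol did not match counts as having no listed region. In a test on simulated data with 19126 genes and 100 lists of 30 genes, 2 unchanged lists were called at p under 0.05, and 98 of 100 were called when the chance of having a region was cut to 50%. That test covered the presence of any region, lists of 30 genes and an unadjusted p. It does not show how often a shortage of promoter regions, or a change in a shorter list, would be called. Random lists are not clustered on chromosomes as protocadherin, homeobox or olfactory receptor genes are, so p-values for clustered lists are too small.

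The planned rule for named genes ranked promoters by fold change and could not be applied in full. The 6 fixed genes (ADIPOQ, LEP, PPARG, FABP4, CEBPA, DNMT1) are reported as planned. Up to 10 protein-coding genes per pass are named by the promoter base pairs that a region covers, and up to 4 members per list are chosen with promoter regions first and then by number of regions. Both replacements were set after the columns were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives tried were a 50% overlap, counting every class a region touches, protein-coding transcripts only, regions of 150 bp only, other backgrounds and length bins for the lists, and leaving out long stretches without a listed region. For each stretch, the skipped numbers of a pass were counted between that pass's own nearest listed regions on either side. These can lie farther apart than the stretch, so each count is an upper limit for the stretch itself.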

Results

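Methyl-capture sequencing was carried out on human subcutaneous adipocytes differentiated from primary preadipocytes and exposed to DMSO (2 samples) or to 100 nM guadecitabine (2 samples), with DNA taken on day 4. The design asks which parts of the adipocyte methylome differ after exposure to a DNA methyltransferase inhibitor. The table analysed here gives the positions and gene annotation of regions obtained from these 4 samples, with no value per sample. The difference between guadecitabine and DMSO, its direction and its error between replicates were therefore not analysed here, and the results below describe where the regions lie.

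The table held 210730 distinct regions, of which 204468 lay on the 22 autosomes and overlapped 58362 transcripts of 25353 genes. Every region began on a 50 bp grid. The median autosomal region was 200 bp wide, 75594 regions (37.0%) had the minimum width of 150 bp, and 321 reached 1000 bp or more. Together they covered 50.8 Mb. The widest was 2800 bp, in TMEM163 (chromosome 2, 134606601 to 134609400), followed by 2700 bp in SNTG2 (chromosome 2, 1106301 to 1109000). A 2300 bp region of the first pass lay on chromosome 1 (629101 to 631400) in the transcripts AC114498.1 and RP5-857K21.4. As background knowledge, that stretch holds a copy of mitochondrial DNA, so the placement of its reads is uncertain. A 2100 bp region lay in CARD9 (chromosome 9, 136363951 to 136366050), which encodes a signalling adaptor of innate immunity.

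The authors' numbers passed through the chromosomes 2 times. The first pass held 43896 of the listed autosomal regions (21.5%) and the second 160572 (78.5%). Regions of the first pass were 216 ± 90.3 bp wide and those of the second 257 ± 132 bp (SD over regions). Of 19126 autosomal protein-coding genes, 15658 (81.9%) had at least 1 listed region, 10637 had a region of the first pass and 10177 had regions of both. The median gene with any region had 6. The genes with most regions were large ones. PTPRN2, a receptor-type phosphatase, had 324 regions, CDH4, a cadherin, had 271, and AGAP1 had 260. CAMTA1 had 255, SHANK2 and TRAPPC9 had 241 each, and SORCS2 had 223. All of these genes had regions of both passes, with 85 of the first pass in PTPRN2 and 44 in CDH4.

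The adipocyte genes fixed before the data were examined differed in how many regions they carried, counted without scaling to gene length. Longer genes held more regions. In 5 classes of gene length, the longest (median 153 kb) held 104847 regions and the shortest (median 3.19 kb) 3389. PPARG, the master transcription factor of adipogenesis, had 14 regions between positions 12293051 and 12425950 of chromosome 3, 5 of the first pass and 9 of the second. One of the first pass (12379701 to 12379850) lay with 98% of its length in exon 3 of the transcript ENST00000397010.6, and the others lay wholly in introns. ADIPOQ, which encodes adiponectin, had 2 regions of 150 bp, both in intron 1 and of the second pass (chromosome 3, 186845101 to 186845250 and 186850001 to 186850150). LEP, which encodes leptin, had 1 region in intron 1 (chromosome 7, 128243151 to 128243350) and 1 over its 3′ end (128257501 to 128257750), with 51.2% of its length in exon 3. Both LEP regions belonged to the second pass, which held 78.5% of all listed autosomal regions. DNMT1, the maintenance methyltransferase that the drug depletes, had 16 regions, 4 of the first pass and 12 of the second, and none of them was in a promoter. The largest DNMT1 region (750 bp, chromosome 19, 10184251 to 10185000) lay in intron 1. No listed region overlapped a transcript of FABP4 or CEBPA in the table as analysed here.

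**Figure D1:**
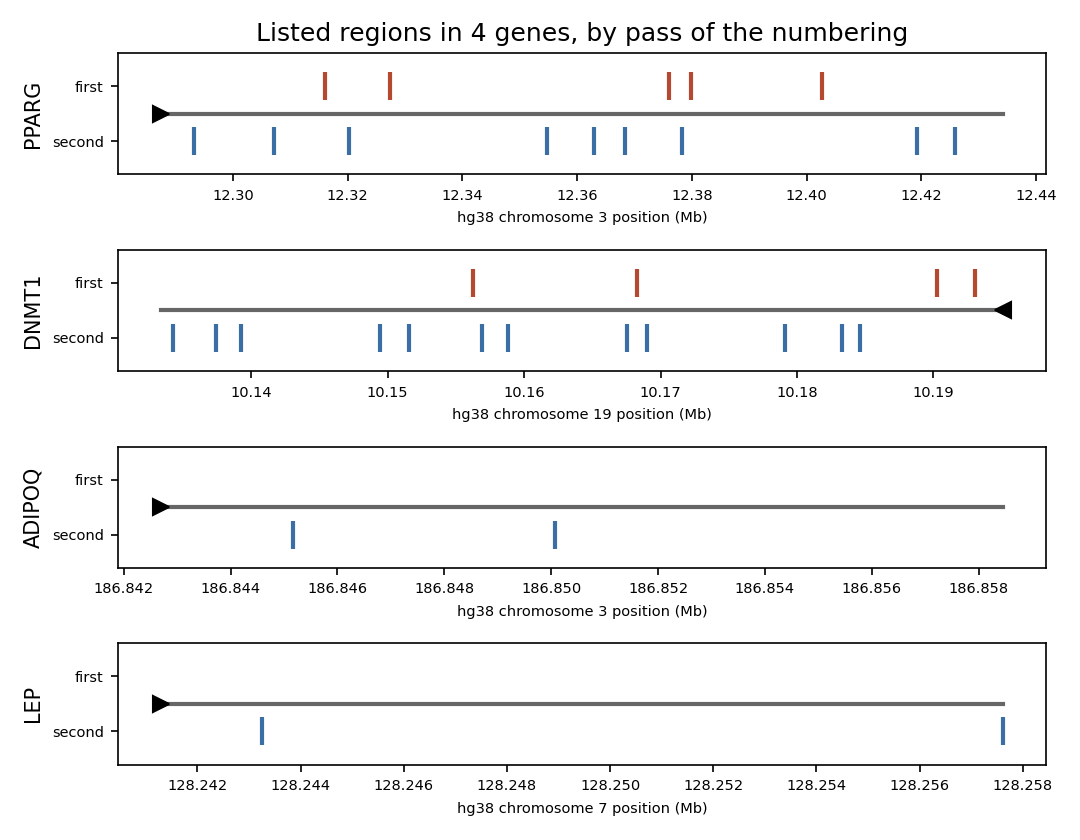
Positions of listed regions (ticks) along the longest overlapped transcript (grey line, arrowhead at the transcript start) of PPARG, DNMT1, ADIPOQ and LEP, on hg38 coordinates in Mb. Upper ticks are regions of the first pass and lower ticks of the second. PPARG and DNMT1 carried both kinds, while the 2 regions of ADIPOQ and the 2 of LEP were of the second pass. The second pass held 78.5% of all listed autosomal regions, and the numbers are not scaled to transcript length.

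Introns held most of the listed regions. No share expected from the lengths of introns, exons, 3′ ends and promoters was computed, so these shares show no preference for a class. By priority, 169041 regions were intronic (82.7%, interval 82.5% to 82.8%, SD 4.11 over autosomes), 19899 lay in exons (9.73%, interval 9.60% to 9.86%, SD 2.17), 10322 at 3′ ends (5.05%, interval 4.95% to 5.14%, SD 1.45) and 5206 in promoters (2.55%, interval 2.48% to 2.62%, SD 0.662). The class rule sets these shares beyond their intervals: exons held 5.09% with at least 50% of a region required and 15.7% when every class touched was counted, and promoters held 1.38% with protein-coding transcripts alone. Promoters had 2.26% of the regions of the first pass and 2.62% of those of the second. The mean difference per autosome was -0.33 ± 0.44 percentage points (first minus second, SD, n = 22), lower in 17 of 22 autosomes (permutation test with sign flips, adjusted p = 0.00282). Exons were lower in the first pass by the same permutation test (-0.78 ± 1.05 points, lower in 18 of 22, adjusted p = 0.00282), as were 3′ ends (-0.49 ± 0.57 points, lower in 18 of 22, adjusted p = 0.00098), and introns were higher (1.60 ± 1.32 points, adjusted p = 0.00024). None of the 4 differences passed the permutation test among regions of 150 bp alone, where the promoter difference was -0.22 points (adjusted p = 0.0983), the exon difference -0.11 points (adjusted p = 0.754), the 3′ end difference -0.47 points (adjusted p = 0.0983) and the intron difference 0.80 points (adjusted p = 0.103). By the same permutation test the promoter difference was lost with protein-coding transcripts alone (-0.10 points, adjusted p = 0.226). With at least 50% of a region required in a class, the exon and intron differences were 0.28 and 0.35 points (permutation test, adjusted p = 0.2101 for both). The promoter and 3′ end differences passed in that setting, at -0.265 and -0.361 points (permutation test, adjusted p = 0.0197 and 0.0184). When every class touched was counted, the intron difference turned to -0.11 points (lower in 13 of 22, permutation test, adjusted p = 0.394).

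Regions were sparse next to transcript starts. In the longest transcript of each of 12784 protein-coding genes with a listed transcript of 10 kb or more, the first 1 kb held 80.3 region midpoints per kb per 1000 transcripts (SD 23.7 over autosomes). The stretch from 5 to 10 kb held 210 (SD 52.6). The ratio was 0.383, and the density near the start was lower in 22 of 22 autosomes (permutation test with sign flips, p = 1e-05, the smallest it can give). Both passes showed it, with a ratio of 0.429 in the first pass and 0.373 in the second. Only transcripts with at least 1 listed region enter this count.

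**Figure D2:**
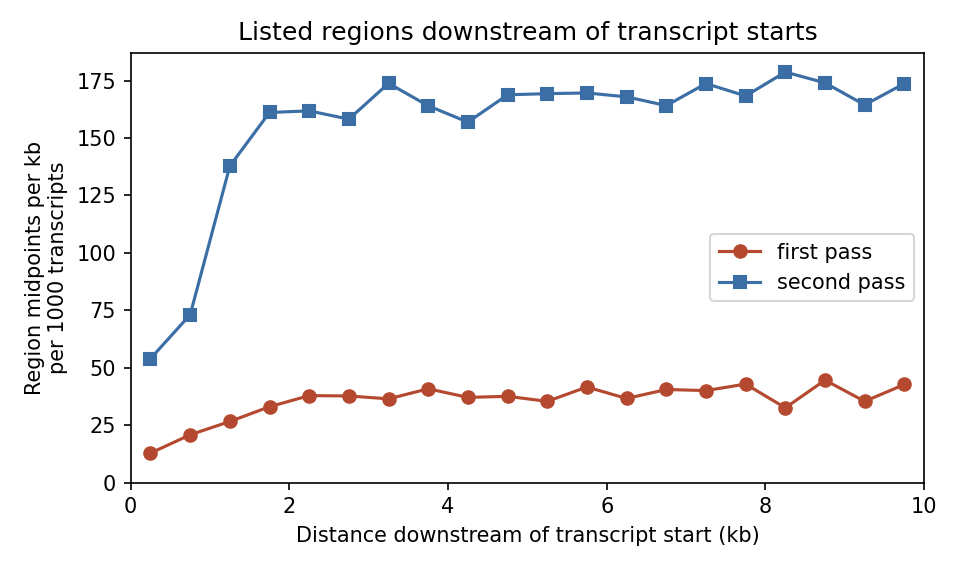
Density of region midpoints (per kb per 1000 transcripts, vertical axis) against distance downstream of the transcript start (kb, horizontal axis, bins of 500 bp) in the longest transcript of 12784 protein-coding genes, for each pass. In the bin next to the start, the density was 12.8 in the first pass and 54.0 in the second, while no bin beyond 5 kb fell below 32.5 and 164, respectively.

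Among the 15 fixed gene lists, genes of the germline programme that are known to be silenced in somatic cells by promoter methylation were the list with an excess of promoter regions. Of 26 germline genes, 13 had a promoter region, against 2.82 in length-matched random lists, of which 95% fell between 0 and 6 (permutation of list membership within length bins, p = 0.0002, the smallest it can give, adjusted p = 0.003). They included the piRNA pathway genes ASZ1, PIWIL2, TDRD1, TDRD9 and MOV10L1, the meiosis genes HORMAD1, SYCE1 and SPATA22, the germ cell RNA regulators DDX4 and BOLL, and SOHLH2, TEX101 and TUBA3C. With at least 50% of the region required in the promoter, 11 had one, against 2.40 in random lists (permutation test, adjusted p = 0.003). TDRD1 and MOV10L1 fell out, with 26% and 28.55% of their regions in a promoter. A promoter of any transcript counts, and random lists were not matched on the number of transcripts. The list was defined by promoter methylation in somatic cells, and the assay captures methylated DNA. If the listed regions are all methylated regions, which is not known, the excess follows from that definition. It therefore shows no effect of the drug. Of the 17 promoter regions of the germline genes, 5 were of the first pass and 12 of the second. PIWIL2, a piRNA-binding Argonaute protein, had a 250 bp region wholly in its promoter (chromosome 8, 22275351 to 22275600, second pass). ASZ1 had one of 150 bp (chromosome 7, 117427201 to 117427350, first pass). SPATA22 had one of 400 bp (chromosome 17, 3513651 to 3514050, first pass). In TEX101 a region of the second pass (chromosome 19, 43414851 to 43415100) directly adjoined one of the first (43415101 to 43415250). The list as a whole had 25 of 26 genes with any region, against 22.6 in random lists (permutation test, adjusted p = 0.921), and 21.9% of its regions were of the first pass, against 19.7% (adjusted p = 0.559).

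**Figure D3:**
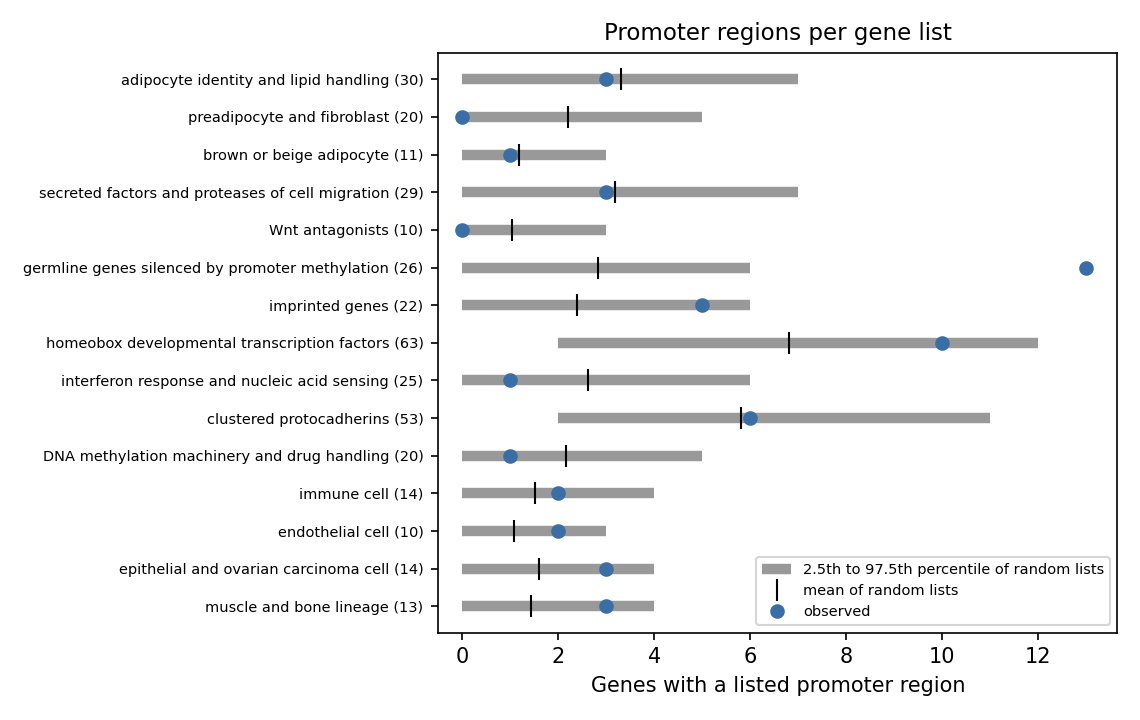
Number of genes with a listed promoter region (horizontal axis) in each of 15 gene lists, with the number of members tested in brackets. Dots are the observed numbers, vertical ticks the mean and grey bars the central 95% of 10000 length-matched random lists. The germline list (13 genes) lies outside its bar.

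None of the 15 lists passed the permutation test for any region or for the share of the first pass, and the germline list alone passed it for promoter regions. At an unadjusted p under 0.05 the permutation test gave 0 lists for any region, 1 for the share of the first pass and 1 for promoter regions. Of 30 genes of adipocyte identity and lipid handling, 23 had any region (23.5 in random lists) and 3 had a promoter region (3.31, permutation test, adjusted p = 1). Promoter regions lay in SREBF1, a regulator of lipid synthesis with 2 of them (1 of 200 bp, chromosome 17, 17819951 to 17820150), in PLIN4, a lipid droplet protein (350 bp, chromosome 19, 4517501 to 4517850), and in LGALS12 (200 bp, chromosome 11, 63506401 to 63506600, first pass). ACACA, the enzyme of the committed step of fatty acid synthesis, had 53 regions, none in its promoter. Of 20 preadipocyte and fibroblast genes 16 had a region and 0 had a promoter region, against 2.21 in random lists (permutation test, unadjusted p = 0.196, adjusted p = 0.965). The collagen gene COL5A1 alone had 106 regions and COL6A3 had 16. Among brown and beige adipocyte genes, 10 of 11 had a region. PRDM16, a determinant of brown fat identity, had 166 regions, EBF3 had 47, and EBF2 had 30, with 1 of 400 bp wholly in its promoter (chromosome 8, 26041151 to 26041550). Numbers of regions per gene, here and below, were not set against gene length, with which they rise.

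Of 29 secreted factors and proteases of cell migration, 23 had a region (22.1 in random lists) and 3 a promoter region (3.18, permutation test, adjusted p = 1). These were the cytokine gene TNF (300 bp, chromosome 6, 31575451 to 31575750), LCN2 (200 bp, chromosome 9, 128149101 to 128149300) and the protease gene MMP11 (300 bp, 6% of it in the promoter, chromosome 22, 23773301 to 23773600), all of the second pass. ADAM12, a metalloprotease gene, had 74 regions and TIMP2, a metalloprotease inhibitor, had 29, with none in a promoter. Of 10 Wnt antagonists 8 had a region and 0 a promoter region (1.04 in random lists, permutation test, unadjusted p = 0.6555). Even 0 could not be called in a list this small. SFRP1 had 8 regions, all of the second pass, including 1 of 1150 bp in intron 2 (chromosome 8, 41279951 to 41281100), and DKK2 had 16. Of 20 genes of DNA methylation and drug handling, 20 had a region (18.6 in random lists). UHRF1, the partner of DNMT1 at replicated DNA, had 31 regions, with 1 in its promoter (300 bp, chromosome 19, 4903351 to 4903650). DNMT3A, a de novo methyltransferase, had 50, and CDA, the deaminase that inactivates decitabine, had 9.

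Imprinted genes had promoter regions in 5 of 22 members (2.40 in random lists, permutation test, adjusted p = 0.965), namely MEST, PLAGL1, MKRN3, PEG10 and NAP1L5. MEST had 2, and the one of 350 bp lay wholly in the promoter (chromosome 7, 130491101 to 130491450). KCNQ1 had 126 regions, 37 of the first pass. Among 63 homeobox and other developmental transcription factors, 10 had a promoter region (6.81 in random lists, permutation test, adjusted p = 0.965). With at least 50% of the region required in the promoter, 6 had one, against 5.95 in random lists. TBX15, a regulator of adipose and skeletal development, and HOXB3 had the regions of the second pass that covered most promoter base pairs, 1250 bp (chromosome 1, 118989151 to 118990400) and 1150 bp (chromosome 17, 48578901 to 48580050). Interferon and nucleic acid sensing genes had a promoter region in 1 of 25 members, MX1 (200 bp, chromosome 21, 41431951 to 41432150). In the clustered protocadherins 47 of 53 members had a region and 6 a promoter region (5.80 in random lists), but these were 71 distinct regions shared among overlapping transcripts.

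Markers of other cell types were not set apart from random lists. Promoter regions were found in 2 of 14 immune genes (CD8A and CD3E, both of the first pass), 2 of 10 endothelial genes (CDH5 and CLDN5), 3 of 14 epithelial and ovarian carcinoma genes (GRHL2, PAX8 and CLDN4) and 3 of 13 muscle and bone genes (ACAN, MYOG and MYF5), with adjusted p between 0.965 and 1 in the permutation test. With at least 50% of the region required in the promoter, the muscle and bone count fell to 1 and the endothelial count to 1, since the regions of ACAN, MYF5 and CDH5 lay with 16.6%, 7.33% and 49.3% of their length in the promoter. The first pass made up 33.3% of the regions in immune genes, against 19.6% in random lists (permutation test, unadjusted p = 0.0224, adjusted p = 0.336). A region in a gene of another cell type does not show that such cells were present, since the assay captures methylated DNA.

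The promoters most covered by a region of the first pass were those of TERB2, a meiotic telomere protein (651 bp of an 800 bp region, chromosome 15, 44956551 to 44957350), MBD3L5 (650 bp, chromosome 19, 7030001 to 7030650), CYTIP (600 bp), GCSAML (551 bp), ARHGEF5 and UGT8 (550 bp each), GALR3 (500 bp), CCDC88B (480 bp), and GFI1B and LPAR5 (450 bp each). MBD3L5 has near-identical copies on chromosome 19, so its region is uncertain. In the second pass, TBX15 and HOXB3 were followed by RALGDS (1000 bp), TMPRSS9 (950 bp), KCNJ18 (922 bp), COL20A1 (900 bp), SCGB1A1 (900 bp), DCAF4 (888 bp), EXOC3 (850 bp) and FAAP100 (800 bp). KCNJ18 also has a near-identical relative.

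Skipped numbers were taken as regions that overlap no transcript, which was not checked. On that reading, regions of the first pass overlapped transcripts less often than regions of the second. Of at least 105024 numbered autosomal regions of the first pass, 43896 (41.8%, interval 41.5% to 42.1%) overlapped a transcript, against 160572 of at least 262865 of the second (61.1%, interval 60.9% to 61.3%). Over autosomes the shares were 42.1% ± 9.86 and 60.8% ± 4.50 (SD, n = 22). The difference of -18.7 ± 9.06 points was negative in 22 of 22 autosomes (permutation test with sign flips, p = 1e-05, the smallest it can give). It ranged from -3.52 points on chromosome 14 to -41.1 points on chromosome 18. The small differences on chromosomes 13, 14 and 15 depend on leaving out the numbers between chromosomes. With the upper bound of the totals they were -29.9, -30.3 and -20.2 points, in place of -6.11, -3.52 and -4.58. The upper bound counts each number between neighbouring chromosomes in both of them, so these values are extremes that cannot all hold together.

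Much of this difference lay around 1 stretch on most chromosomes. Across the longest stretch of each autosome without any listed region, between the nearest listed regions of the same pass on either side, the numbering skipped 27886 regions of the first pass in total and 1878 of the second. These were 45.6% and 1.84% of all skipped numbers counted on the autosomes in each pass. Those flanking regions can lie outside the stretch (on chromosome 11 the stretch was 5.38 Mb and the first-pass interval 8.72 Mb), so the counts are upper limits for the stretches. On 19 autosomes the count was between 778 and 4137 for the first pass, while the second pass had at most 161 on any autosome. As background knowledge, the centromeres of those 19 chromosomes lie in these stretches. No centromere annotation was used here. On chromosome 18, across the stretch from 15100101 to 20947500, the counts were up to 4137 regions of the first pass (interval of 5.99 Mb) and 80 of the second. On chromosome 20, across the stretch from 26247151 to 30286250, they were up to 1994 and 103. On chromosomes 13, 14 and 15 the longest stretch lay elsewhere, with at most 92 regions of the first pass. The second pass had more there on chromosome 13 (119 against 92) and chromosome 14 (62 against 34). The numbers before the first listed region of these chromosomes fall outside this count. Between the last listed region of chromosome 12 and the first of chromosome 13 the numbering skipped 1248 regions of the first pass and 30 of the second. The corresponding numbers were 1222 and 61 between chromosomes 13 and 14, and 957 and 51 between chromosomes 14 and 15. Counts over the 22 autosomes were 1268 ± 821 for the first pass and 85.4 ± 38.7 for the second (SD, higher in the first pass on 20 of 22, permutation test with sign flips, p = 1e-05). With these counts left out, the shares overlapping a transcript were 56.9% and 61.5%, and the difference per autosome was -4.36 ± 1.73 points (lower in 22 of 22).

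**Figure D4:**
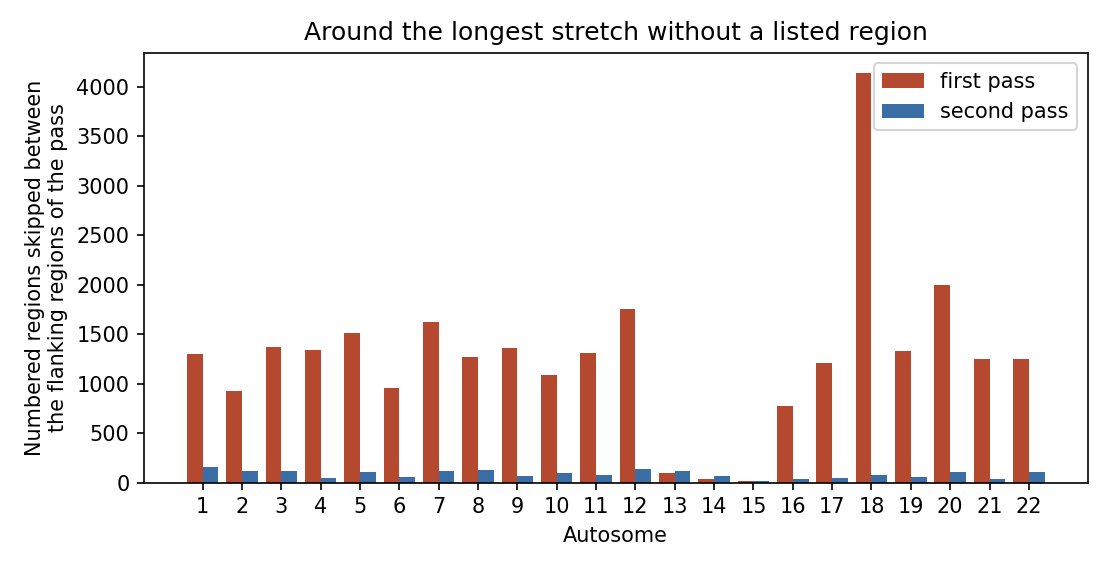
Number of regions that the authors' numbering skips (vertical axis) between the listed regions of each pass that flank the longest stretch without a listed region on each autosome (horizontal axis). The bars of the first pass reach 778 to 4137 on 19 autosomes, against at most 161 for the second pass. Chromosomes 13, 14 and 15 have at most 92 in the first pass, and the 1248, 1222 and 957 regions skipped before their first listed region are not drawn.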

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

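The alternatives that need a value per sample (other scalings, pseudocounts, filters on low values, thresholds, other tests, leaving out a replicate) were not run, since the table gives none. No paired analysis was possible because the table holds no value for any of the 4 samples, so the fit with the replicate number as a block could not be made. Alternatives for the transcript types, the 150 bp width, the region totals, the stretches, the transcript choice, the far window, the length bins, the 50% promoter overlap of the lists and the minimum number of regions were chosen after seeing the data; the overlap and class alternatives for the gene contexts and the background of the lists were planned. Counting protein-coding transcripts only, the promoter share was 1.38% in place of 2.55%, and the promoter difference between passes was -0.10 points (no longer past the threshold). With regions of 150 bp only, the differences (first minus second) in promoters, 3′ ends, exons and introns were -0.22, -0.47, -0.11 and 0.80 points, none past the threshold, and the first pass made up 27.4% of listed regions in place of 21.5%; narrow regions are more common in the first pass. With at least 50% of the region required, the exon share was 5.09% and the intron share was 88.0%. The intron difference was then 0.35 points, and the exon difference changed sign to 0.28 points (neither past the threshold). The promoter and 3′ end differences stayed past the threshold in that setting. The cause of the changes up to here was not tested. Counting every class a region touches, the exon share was 15.7%, the intron share was 95.7%, and the intron difference changed sign to -0.11 points and was no longer past the threshold, because almost every region then counts as intronic. The deficit of the first pass in transcripts stayed past the threshold throughout. It was -22.1 points with the upper bound of region totals, which counts each number between neighbouring chromosomes in both of them. It was -4.36, -4.32 and -3.59 points without the longest stretches, stretches of 2 Mb and stretches of 1 Mb. The start-site ratio was 0.525 with the shortest transcript and 0.398 with a far window of 2 to 5 kb. The number of gene lists past the promoter test was 1 as reported and 1 with each of 10 length bins, a 50% overlap and a background of genes with a listed region. The number of genes departing from the pooled share of the first pass was 9 with at least 20 regions per gene, 7 with at least 10 and 6 with at least 40. Depth per sample is unknown, so which regions could have been missed for lack of reads cannot be said.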

Other observations

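Chosen only after the result was seen were the tests of the gene families, of the numbering, of the long stretches, of mixing by distance and of the odds of a call for genes with tandem copies. Region width, gene-poor chromosomes, chance mixing, the calls left without tandem copies and neighbouring genes had their bounds written first. Gene families defined by symbol (12, adjusted together) were set against the same length-matched random lists. Olfactory receptor genes, which encode odorant receptors of the nasal epithelium, had a listed region in 74 of 391 members, against 190 in random lists (permutation test, adjusted p = 0.0024). Histone genes had one in 14 of 80 members, against 24.5 (permutation test, adjusted p = 0.013), and a promoter region in 2, against 9.80 (adjusted p = 0.0192). Keratin-associated proteins of the hair shaft had a region in 36 of 94 members, against 21.4 (permutation test, adjusted p = 0.004), and a promoter region in 23, against 11.7 (adjusted p = 0.012). Solute carriers had a region in 317 of 338 members, against 300.2 (permutation test, adjusted p = 0.004), and cytosolic ribosomal proteins in 59 of 76, against 46.2 (adjusted p = 0.0048). Mitochondrial ribosomal proteins had a promoter region in 2 of 77 members, against 8.48 (permutation test, adjusted p = 0.0488). Zinc finger genes had a region in 457 of 505, against 445 (permutation test, adjusted p = 0.156). Collagens, potassium channels, classical cadherins, taste receptors and calcium channels did not pass for any measure. Histone names were matched through synonyms. Several of these families lie in clusters, so their p-values are too small.

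What the 2 passes of the numbering stand for is a matter for the authors' own records, but the positions bear on it. If they were separate lists called independently, such as 1 per group, their regions would overlap each other. The count was 0 overlapping pairs, against 1310 on average and at least 1202 in 100 random shifts along the chromosomes, which argues against it. Neighbouring regions less than 200 bp apart belonged to different passes in 99.9% of 3450 pairs, against 33.1% of all neighbouring pairs. Classes of one segmentation, joined only within a class, would give this. Separate lists, each joined over short gaps, would give it too, so this share does not tell them apart. Whether the passes are the 2 directions of the drug effect cannot be told apart from other meanings, since 0 columns name a group or direction.

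The deficit of the first pass in transcripts was set against 3 explanations. It rests on the unchecked reading of skipped numbers as regions without a transcript. For region width, only the part due to regions reaching partly into a transcript could be tested. Partly overlapping regions made up 0.199 points of the difference of -19.3 points, which argues against that part. The widths of skipped regions are unknown, so the passes were not compared at equal width, and width stays open otherwise. Gene-poor chromosomes were argued against, since the deficit held within 22 of 22 autosomes. One long stretch without a listed region per chromosome does not account for all of the deficit. Of the mean of -18.7 points, -4.36 remained once the numbers skipped across those stretches were left out. The few regions left out on chromosomes 13, 14 and 15 (at most 92 of the first pass) do not bear on this. The 1248, 1222 and 957 first-pass numbers skipped before their first listed region were already outside the totals. By background knowledge the stretches of the other 19 autosomes hold satellite DNA, whose methylation and whose read placement both stay open, and no biological explanation was tested.

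Of 2438 genes with at least 20 regions, 9 departed from the pooled share of the first pass, 21.5% (exact binomial test, Benjamini-Hochberg adjusted p under 0.05, regions taken as independent), and 213 did at an unadjusted p under 0.05. Shuffling the passes within chromosomes gave at most 1, so chance mixing region by region is argued against for the 9 as a set. The shuffle also breaks up short-range clumping of a pass (28.8% of neighbouring pairs 200 to 1000 bp apart were mixed, against 33.7%). It therefore cannot tell whether such clumping raised the number of calls. NBPF20 had 31 of 34 regions in the first pass, NBPF19 had 36 of 52 and NBPF14 had 17 of 33, while USP17L15 had 2 of 68, and all 4 have a gene of the same symbol stem among the 10 nearest coding genes on either side. Reads shared between tandem copies is a candidate explanation for these 4, since such genes were called more often (odds ratio 11.5, Fisher's exact p = 0.00182). That test takes genes as independent, while NBPF20, NBPF19 and NBPF14 belong to 1 family on chromosome 1, so its p is too small. The NBPF genes had more regions of the first pass and USP17L15 had fewer. For the other 5 (TTC34, LPA, CCSER1, HPSE2 and LINGO2), which outnumber the shuffles, it stays open against the bound set beforehand, because symbol stems miss copies under other names and repeats within a gene. Stretches of chromosome that go one way stay open too: Spearman's rho over 4827 pairs of neighbouring genes, which are not independent, was 0.0824 (permutation p = 1e-04, the smallest it can give), below the preset 0.1, but the pairs cover all genes with at least 10 regions and not the 5, and the margin allowed for its spread was added after the value was seen.

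Neighbouring regions 200 to 1000 bp apart mixed the passes in 28.8% of pairs, against 33.7% for random mixing within chromosomes. The share was 31.0% at 1000 to 5000 bp, 33.9% at 5000 to 20000 bp and 36.0% at 20000 to 100000 bp. The same expected share was used at every distance, so local differences in the share of the first pass were not allowed for.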
